A study of Mus musculus with 12 samples.

How the data were processed

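RNA of 12 mouse lung samples in 4 groups of 3 was compared: 60% or 10% fat diet, each in room air or more than 95% oxygen. The deposited values were RPKM, in a single table with a gene symbol, a position and, for each library, a value and a status. Per the submitters' processing notes, reads were converted with bcl2fastq 2.19 and aligned with TopHat2 2.0.11. The notes name the builds mm8 and mm9 without saying which the positions follow, and the program that made the RPKM is not given in the sources used here. Read counts were not used here, since the table examined holds RPKM only, and no test on counts was run. Rough depths of 20.7 to 27.6 M reads per library were read from the steps between low RPKM values of transcripts of at least 1000 bases, with a length offset chosen on these data; they limit the precision of genes with few reads.

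Of 20793 genes or transcripts in the table, 208 marked as having too little data were left out, and 85 estimates marked as failed, in 26 of them, were treated as missing. Tested were 13324 with an RPKM of at least 1 in at least 3 of the 12 libraries and at least 2 values in each group. A symbol that stood more than once (519 entries, 10 of them tested) was kept as separate entries told apart by position. Values were put on the scale log2(RPKM + 0.5), and no further scaling was applied. limma 3.58.1 in R 4.3.3 fitted a mean per group to all 12 libraries, with moderated variances and a trend on the mean (8 residual and 4.26 prior degrees of freedom). Tests were two-sided with Benjamini-Hochberg adjustment over the tested genes at 0.05. The comparisons were oxygen against room air in each diet, 60% against 10% fat in each exposure and averaged over the exposures, and the interaction, the oxygen effect on 60% fat minus that on 10% fat.

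A set of 37 gene lists for metabolic pathways, stress responses and cell type markers was fixed, of which 2 had fewer than 5 tested members and 7 listed genes were not in the table. The other 35 were tested with camera on 13310 genes with all values, with an inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Named genes followed a rule: in each comparison the 6 largest positive and 6 largest negative log2 changes among genes with an adjusted p under 0.05 and no overlap between the groups (in both exposures for the average, not asked for the interaction), leaving out predicted and unnamed genes and segments of antigen receptors, then the 4 members of each list with the smallest p, and always Fasn, Srebf1, Scd1, Sftpc and Sftpb. Groups, comparisons, tests, lists, this rule and the alternatives were fixed before the data were examined, except for the alternatives that the closing section names as added.

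Alternatives were another pseudocount, other filters on low values, median-ratio scaling, quantile normalization, no trend, robust variances, sample weights, the libraries of a comparison alone, replicate numbers as a block, and each library left out in turn. Whether replicate numbers pair the samples was checked by correlating deviations from group means across genes. Libraries of one exposure with the same number had r from 0.293 to 0.486 (6 pairs), those with the same number across exposures from −0.131 to 0.22 (12 pairs), and those of one exposure with other numbers from −0.304 to 0.0102 (12 pairs). The number was then also fitted as a block within each exposure, which the text calls blocked, for the comparisons that involve diet. Summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The model was tested on simulated data with the same design, 13310 genes and 200 changed. The simulated noise was independent between libraries and genes, without the correlation of equal replicate numbers given above. The shares found thus describe that noise and not the correlated libraries of this study. A log2 change of 1 was found in 89.6% of such genes for the diet in room air and 62.7% for the interaction, and the share of false calls lay between 3.11% and 5.99% over the 6 comparisons. For the block within each exposure, a shared deviation per pair as large as the residual spread was added to that noise. The share of false calls then lay between 3.83% and 6.54% over the 4 comparisons that involve diet. For the blocked interaction a log2 change of 1 was found in 53.7% of such genes and one of 0.5 in 0%. Since the noise differed, the simulated shares with and without the block cannot be compared with each other.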

Results

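RNA of whole lungs from C57BL/6J mice, an inbred laboratory strain, was sequenced in 12 samples that form 4 groups of 3. Mice received a diet of 60% or 10% fat for 12 weeks and were exposed to more than 95% oxygen or room air; the labels leave the order of diet and exposure unclear. The series title names diet-induced obesity and lung injury by high oxygen as its subject. The labels do not give the length of the exposure. The deposited values were RPKM per gene, without read counts. From the steps between low RPKM values, the depth came to a rough 20.7 to 27.6 M reads per library, with group means from 22.2 to 25.7 M reads. Summed RPKM per library ran from 538746 to 731004. The first principal component of the tested genes held 76.4% of the variance and parted the oxygen from the room-air libraries. Pearson's r between libraries of one group, across genes, lay between 0.980 and 0.988 in room air and between 0.990 and 0.995 under oxygen. The labels name separate samples but no animal for each, so p-values measure only the spread between these samples, which may be technical. Gene positions are those of the deposited table, in mm8 or mm9; the sources used here do not say which. Each value is for the whole gene, with no split into exons or untranslated regions.

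The first comparison asked what oxygen changed in the lungs of mice on the 60% fat diet. Gdf15, which encodes a secreted stress-response cytokine (chromosome 8, 73153293 to 73155534), averaged 423 ± 60.6 RPKM (SD, n = 3) under oxygen and 5.09 ± 1.77 in room air, a 78.3-fold rise on the log2(RPKM + 0.5) scale (log2 change 6.29 ± 0.43 SE, adjusted p = 2.16e-07). The tight-junction gene Cldn4 (chromosome 5, 135420993 to 135422804) stood at 143 ± 16.3 RPKM against 2.97 ± 0.266 (5.36 ± 0.12, adjusted p = 6.63e-11). Scgb1a1, the main secretory product of club cells (chromosome 19, 9158132 to 9162446), fell from 136959 ± 37396 to 15809 ± 1192 RPKM (−3.08 ± 0.27, adjusted p = 1.69e-06). Scgb1a1 was named after its values were seen, and quantile normalization, which sets the most abundant genes to the same values, ended its call in both diets (log2 change 0, adjusted p = 1). Its share of the summed RPKM was 20.4 ± 3.60% in room air and 2.92 ± 0.207% under oxygen. The other largest rises were those of Mt2 (5.31), a metallothionein, Prss22 (5.18), Adm2 (4.85) and Sprr1a (4.59). The largest falls were those of Sln (−4.51), Myh6 (−4.48), Mb (−3.92), Csrp3 (−3.84) and Myl4 (−3.59), all known from striated muscle, and of the potassium channel gene Kcnj13 (−3.55).

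Targets of NRF2, the regulator of antioxidant genes, rose in the 60% fat lungs in 25 of 28 tested cases and fell in 1, among them Txnrd1 (log2 change 2.72 ± 0.11), Nqo1 (2.57 ± 0.11) and Gclc (3.44 ± 0.15). Gclc encodes the catalytic subunit of the enzyme that limits glutathione synthesis. The list's median was 1.26 (camera adjusted p = 3.02e-11; adjusted p = 0.109 with an estimated correlation). Of 23 targets of p53, 19 rose and 1 fell, with Gadd45a at 3.21 ± 0.14, Zmat3 at 1.81 ± 0.09 and Mdm2, whose product degrades p53, at 1.27 ± 0.07 (median 1.58, adjusted p = 3.42e-10). That list alone among the 22 called in this comparison kept its call with an estimated correlation (adjusted p = 0.0232). Targets of the stress transcription factor ATF4 rose in 15 of 19 cases with none falling, for example Trib3 (3.36 ± 0.14) and Psat1 (2.59 ± 0.11; median 2.01, adjusted p = 8.61e-10, adjusted p = 0.1 with an estimated correlation). Chaperones of the endoplasmic reticulum moved down: 14 of 20 fell and none rose, or 15 adjusted over the list alone, with Hsp90b1 at −0.91 ± 0.10 (median −0.56, adjusted p = 0.0022, adjusted p = 0.643 with an estimated correlation). In the other lists named for oxygen, the counts adjusted over the list alone were the same unless given.

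Inflammatory and acute-response genes rose in 17 of 28 cases and fell in 3, with Timp1, an inhibitor of matrix proteases, at 159 ± 2.13 against 9.47 ± 0.784 RPKM and the adhesion gene Icam1 at 1.12 ± 0.08 (median 1.19, adjusted p = 8.8e-05, adjusted p = 0.643 with an estimated correlation). Matrix and TGF-beta response genes rose in 13 of 22 cases and fell in 1, among them Cyr61 (3.68 ± 0.17) and the basement membrane collagen Col4a1 (1.85 ± 0.09; median 0.89, adjusted p = 2.46e-05, adjusted p = 0.403 with an estimated correlation). Circadian clock genes rose in 14 of 18 cases and fell in 1 (median 0.61, adjusted p = 0.00506, adjusted p = 0.141 with an estimated correlation). Glucocorticoid-response genes rose in 10 of 12 and fell in 1 (median 1.11, adjusted p = 0.000351, adjusted p = 0.403 with an estimated correlation). Immediate early genes rose in 8 of 13 cases, or 9 adjusted over the list alone, and fell in 1 (median 0.77, adjusted p = 0.0199, adjusted p = 0.643 with an estimated correlation; adjusted p = 0.0794 after quantile normalization, and 0.00719 to 0.643 across alternatives). Interferon-stimulated genes fell in 17 of 24 cases and rose in 3, with Gbp2 at −1.77 ± 0.19 and Ifit3 at 2.17 ± 0.21 (median −0.89, adjusted p = 0.021, adjusted p = 0.648 with an estimated correlation). Of 9 genes of MHC class II presentation, 8 fell (median −0.80, adjusted p = 0.0215, adjusted p = 0.643 with an estimated correlation).

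Of 16 alveolar type 2 markers 15 fell and none rose in the 60% fat lungs under oxygen, including Slc34a2, a phosphate carrier (−2.32 ± 0.22), and Nkx2-1, a lung lineage transcription factor (−1.61 ± 0.10; median −1.38, adjusted p = 1.38e-05, adjusted p = 0.403 with an estimated correlation). Sftpc, the surfactant protein C gene (chromosome 14, 70920749 to 70923888), went from 25644 ± 5672 to 9759.8 ± 1386 RPKM (−1.38 ± 0.22, adjusted p = 0.000168; 1.03e-05 to 0.999 across alternatives, the highest after quantile normalization). Sftpb, the surfactant protein B gene (chromosome 6, 72253242 to 72264364), stood at 1563 ± 457 and 1850.0 ± 379.9 RPKM and was not called (−0.26 ± 0.19, adjusted p = 0.253; 0.0291 without 60% fat oxygen replicate 1, and 0.0291 to 0.723 across alternatives). All 14 ciliated markers fell (median −1.11, adjusted p = 1.25e-05, adjusted p = 0.403 with an estimated correlation). So did 10 of 14 club and secretory markers with none rising, such as Cyp2f2 (−2.83 ± 0.15; median −1.76, adjusted p = 0.00159, adjusted p = 0.643 with an estimated correlation). Type 1 markers went both ways, 4 up and 5 down (adjusted p = 0.868). All 10 cardiac muscle markers fell, Myh6 most (chromosome 14, 55560758 to 55585444; −4.48 ± 0.50, adjusted p = 9.39e-06; list median −3.05, adjusted p = 7.43e-05, adjusted p = 0.403 with an estimated correlation).

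Of 22 T and NK cell markers 17 fell in the 60% fat lungs (adjusted p = 0.00523, adjusted p = 0.643 with an estimated correlation). Of 16 B cell markers 11 fell (adjusted p = 0.0215, adjusted p = 0.663 with an estimated correlation). Endothelial markers fell in 13 of 23 cases and rose in 3, with the apelin receptor gene Aplnr at −3.34 ± 0.26 (adjusted p = 0.0313, adjusted p = 0.648 with an estimated correlation). Fibroblast markers fell in 10 of 16 and rose in 1 (adjusted p = 0.0264, adjusted p = 0.643 with an estimated correlation). Of 7 erythroid markers 6 fell (adjusted p = 0.0404, adjusted p = 0.643 with an estimated correlation). Neutrophil markers fell in 3 of 16 cases, or 1 adjusted over the list alone, and the list was not called (adjusted p = 0.227), nor were the alveolar macrophage markers, 4 up and 4 down of 14 (adjusted p = 0.846). Some of these calls rested on single libraries. Without 60% fat room-air replicate 1 the B cell call was lost (adjusted p = 0.085), and without room-air replicate 2 of that diet the endothelial (0.0863) and fibroblast (0.0535) calls. The erythroid call ended without 60% fat oxygen replicate 1 (0.0514) or 2 (0.0594), and without 60% fat room-air replicate 2 (0.0525) or 3 (0.0718), and with replicate numbers as a block (0.0535). Across alternatives the adjusted p of these 4 lists ran from 0.000752 to 0.663.

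In fat metabolism, 12 of 22 genes of fatty acid synthesis fell in the 60% fat lungs and 3 rose. The list was not called (median −0.30, adjusted p = 0.147). Fasn, the fatty acid synthase gene (chromosome 11, 120667272 to 120685861), fell from 54.5 ± 2.87 to 20.8 ± 4.01 RPKM (−1.39 ± 0.13, adjusted p = 2.67e-06), and the ATP-citrate lyase gene Acly by a log2 change of −0.97 ± 0.07. Scd1, which encodes a desaturase that makes monounsaturated fatty acids (chromosome 19, 44468940 to 44482199), went from 365 ± 24.4 to 231 ± 13.5 RPKM (−0.66 ± 0.16, adjusted p = 0.00292). Srebf1, the gene of the transcription factor SREBP-1 (chromosome 11, 60012591 to 60034106), stood at 28.7 ± 1.26 and 29.9 ± 2.28 RPKM (−0.06 ± 0.08, adjusted p = 0.553). Me1, the malic enzyme gene that yields NADPH, rose (0.89 ± 0.08). Genes of fatty acid oxidation went both ways, 7 up and 10 down of 25 (adjusted p = 0.676). Those of cholesterol synthesis went 9 up and 5 down of 22 (adjusted p = 0.137; 0.0211 without 60% fat oxygen replicate 1, and 0.0211 to 0.743 across alternatives).

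In this comparison limma called 8370 of 13324 genes (62.8%), 3508 higher and 4862 lower under oxygen, and 1988 of the calls were changes of at least 2-fold. The share of calls that were higher was 41.9%, and 49.9% after median-ratio scaling and 50.1% after quantile normalization, so the excess of falls depended on the scaling. At an unadjusted p under 0.05 there were 8852 genes, with 666 expected by chance. In 8856 genes (66.5%) the 3 oxygen and the 3 room-air libraries did not overlap, against 10% by chance.

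**Figure D1:**
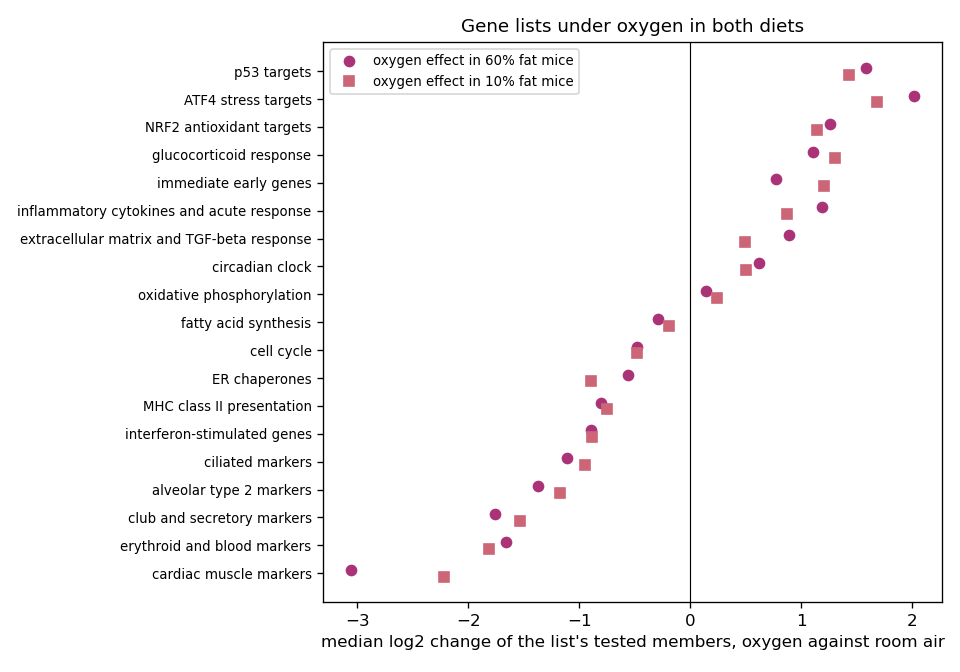
Median log2 change (x axis, oxygen against room air) of the tested members of 19 gene lists (y axis), circles for the 60% fat and squares for the 10% fat diet. The p53 list lies at 1.58 and 1.43 and the cardiac muscle list at −3.05 and −2.22.

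The same question was asked on the 10% fat diet. Gdf15 rose from 7.72 ± 7.01 to 376 ± 63.0 RPKM (56.7-fold, log2 change 5.83 ± 0.43, adjusted p = 5.28e-07), Cldn4 from 3.15 ± 0.545 to 144 ± 9.53 RPKM (5.31 ± 0.12, adjusted p = 7.38e-11). The serine protease gene Prss22 rose by 5.45 ± 0.16. Scgb1a1 fell from 122905 ± 28090.0 to 23856 ± 2068 RPKM (−2.35 ± 0.27, adjusted p = 1.72e-05), with shares of 19.3 ± 3.07% in air and 4.37 ± 0.355% under oxygen. Fasn fell from 77.5 ± 8.15 to 26.7 ± 3.23 RPKM (−1.52 ± 0.13, adjusted p = 1.73e-06) and Scd1 from 653 ± 179.6 to 225.3 ± 21.1 RPKM (−1.50 ± 0.16, adjusted p = 7.24e-06). Srebf1 stood at 28.2 ± 2.13 under oxygen and 30.5 ± 1.01 RPKM in air (−0.11 ± 0.08, adjusted p = 0.243). The other largest rises were Adm2 (4.48), Mt2 (4.45) and Doc2b (3.94), and the largest falls Sln (−3.68), the heat shock gene Hsph1 (−3.33), Kcnj13 (−3.32), the atrial peptide gene Nppa (−3.31), the histone gene Hist2h3c1 (−3.26) and Wnt3a (−3.12).

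Of the stress lists in the 10% fat lungs, 22 of 23 p53 targets rose and 1 fell (median 1.43, adjusted p = 3.68e-11), again the only list of the 19 called that kept its call with an estimated correlation (adjusted p = 0.0181). NRF2 targets rose in 23 of 28 cases, or 24 adjusted over the list alone (median 1.14, adjusted p = 5.05e-12, adjusted p = 0.0924 with an estimated correlation). ATF4 targets rose in 17 of 19 (median 1.68, adjusted p = 3.68e-11, adjusted p = 0.0691 with an estimated correlation). Chaperones of the endoplasmic reticulum fell in 19 of 20 cases and rose in 1 (median −0.90, adjusted p = 1.28e-05, adjusted p = 0.577 with an estimated correlation), Pdia4 at −1.81 ± 0.13. Inflammatory genes rose in 13 of 28 cases and fell in 2 (adjusted p = 0.00301, adjusted p = 0.594 with an estimated correlation). Matrix and TGF-beta response genes rose in 11 of 22 with 1 falling (adjusted p = 6.31e-05, adjusted p = 0.450 with an estimated correlation). Immediate early genes rose in 12 of 13 with 1 falling, Egr1 at 3.36 ± 0.34 (median 1.20, adjusted p = 6.31e-05, adjusted p = 0.450 with an estimated correlation). Genes of cholesterol synthesis rose in 12 of 22 cases and fell in 4, with the lanosterol synthase gene Lss at 2.03 ± 0.12 (adjusted p = 0.00494, adjusted p = 0.594 with an estimated correlation). Those of fatty acid synthesis fell in 10 of 22 and rose in 2, a list that was not called (median −0.19, adjusted p = 0.104; 0.0335 after quantile normalization, and 0.0335 to 0.594 across alternatives).

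Alveolar type 2 markers fell in 14 of 16 cases with none rising (median −1.18, adjusted p = 1.61e-05, adjusted p = 0.450 with an estimated correlation). All 14 ciliated markers fell (median −0.95, adjusted p = 1.61e-05, adjusted p = 0.450 with an estimated correlation). Club and secretory markers fell in 8 of 14 and rose in 1 (adjusted p = 0.00494, adjusted p = 0.594 with an estimated correlation). Sftpc went from 25205 ± 4209.9 to 12414 ± 1593 RPKM (−1.02 ± 0.22, adjusted p = 0.00172); without the filter on low genes that p was 0.0721, and across all alternatives it ran from 0.000279 to 0.999. Sftpb stood at 1797 ± 178 and 1893 ± 167 RPKM (−0.08 ± 0.19, adjusted p = 0.753). All 10 cardiac muscle markers fell (median −2.22, adjusted p = 0.000336, adjusted p = 0.466 with an estimated correlation). The endothelial list was not called in this diet (2 up and 10 down of 23, adjusted p = 0.126; 0.0371 without 10% fat room-air replicate 2, 0.00414 after quantile normalization, and 0.00414 to 0.730 across alternatives). Fibroblast markers (3 up and 7 down of 16, adjusted p = 0.147) and T and NK cell markers (1 and 10 of 22, or 1 and 9 adjusted over the list alone, adjusted p = 0.164) were not called as lists either. Nor were B cell markers (2 up and 2 down of 16, or 1 and 1 adjusted over the list alone, adjusted p = 0.998), with a median of −0.13 and a camera direction of higher. Whether these lists differed between the diets is tested with the interaction below.

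In the 10% fat lungs limma called 7923 genes (59.5%), 3366 higher and 4557 lower, with 1688 changing at least 2-fold. Here 42.5% of the calls were higher, and 49.7% after median-ratio scaling and 50.5% after quantile normalization. There were 8521 genes that had an unadjusted p under 0.05, and in 8990 (67.5%) the groups did not overlap, against 10% by chance. The responses of the diets, which shared no library although libraries of equal number within an exposure were correlated, correlated across genes with Pearson's r = 0.927 and Spearman's rho = 0.918; genes are not independent replicates. Called in both diets were 6855 genes, 2874 of them higher in both, 3974 lower in both and 7 in opposite directions. Independent lists of these sizes would share 886 higher and 1663 lower genes.

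**Figure D2:**
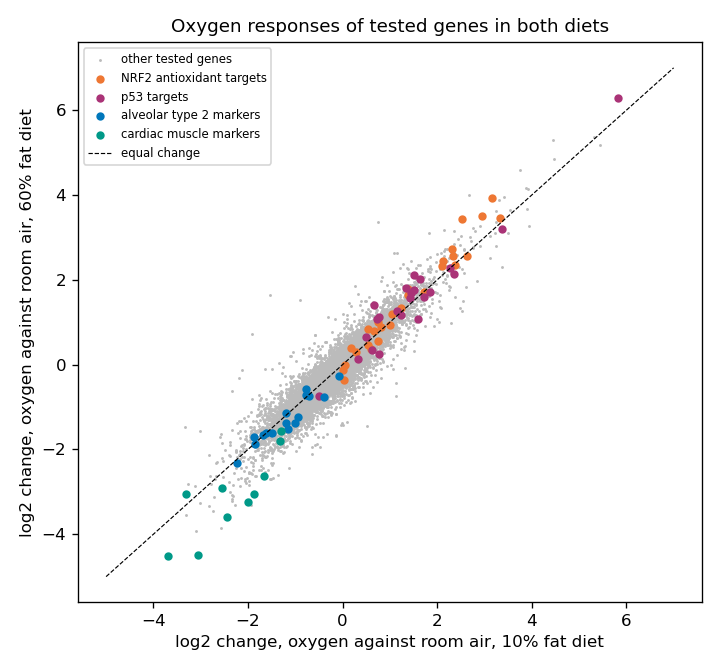
Log2 change under oxygen of each tested gene on the 10% fat (x axis) and 60% fat diet (y axis); colours mark NRF2 targets, p53 targets, alveolar type 2 and cardiac muscle markers, and the dashed line marks equal changes. The points follow the line (r = 0.927 across genes), with the p53 targets to the upper right and the cardiac markers to the lower left.

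**Figure D3:**
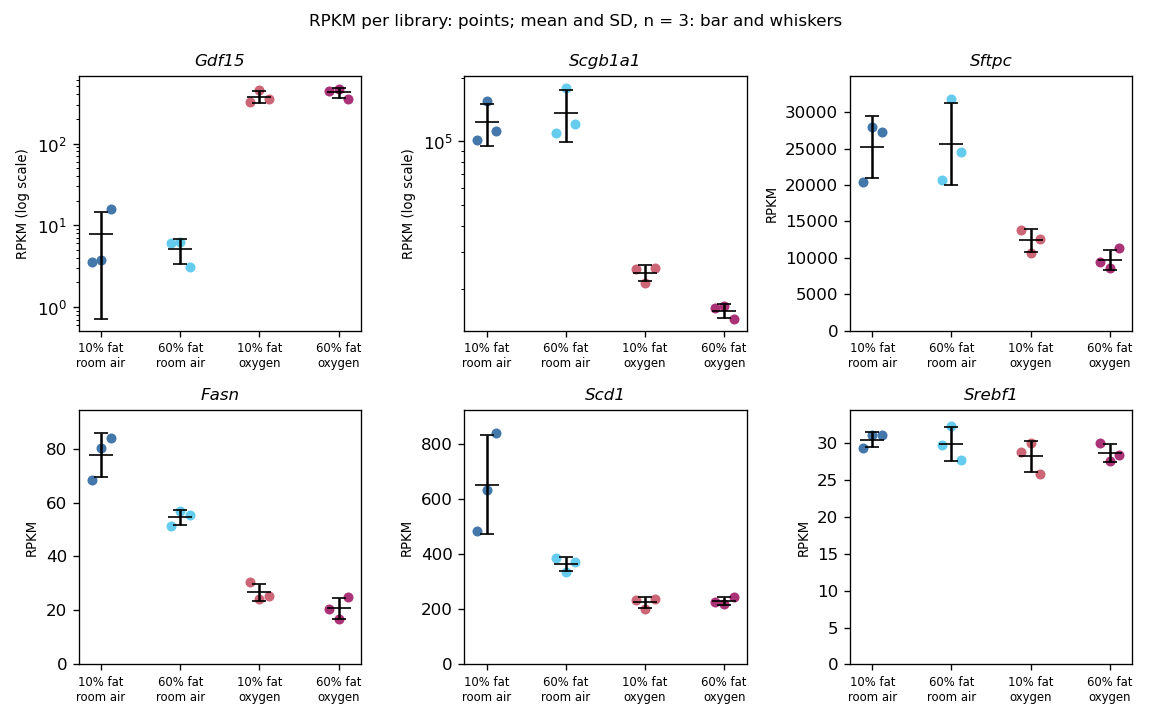
RPKM of 6 genes per library in the 4 groups, points for libraries, bars for means and whiskers for the SD (n = 3); the axes for Gdf15 and Scgb1a1 are logarithmic. Fasn lies highest in 10% fat room-air lungs (77.5 ± 8.15) and lowest under oxygen on 60% fat (20.8 ± 4.01), while Srebf1 means stay between 28.2 and 30.5.

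A further comparison asked what the diet changed in room air. Among single genes, the B cell receptor gene Cd79b, the homing receptor gene Cxcr5 and Mfap4 were higher on the 60% fat diet and Lyve1 was lower. Cd79b (chromosome 11, 106172655 to 106175843) averaged 37.7 ± 11.3 RPKM on 60% fat and 12.9 ± 3.16 on 10% fat (log2 change 1.49 ± 0.21, adjusted p = 0.0231). Cxcr5, a follicle-homing receptor gene (chromosome 9, 44319870 to 44334504), averaged 7.51 ± 2.72 and 2.06 ± 0.650 RPKM (1.61 ± 0.23, adjusted p = 0.0231). The elastic fibre gene Mfap4 (chromosome 11, 61298946 to 61302206) averaged 901 ± 214 and 348 ± 48.3 RPKM (1.35 ± 0.17, adjusted p = 0.0138). Lyve1, a lymphatic vessel and macrophage marker (chromosome 7, 117994121 to 118006467), was lower, at 86.4 ± 13.8 against 198 ± 28.6 RPKM (−1.20 ± 0.13, adjusted p = 0.00552). Of the 20 genes called, 13 were higher, among them also Apoc2 (1.66), Treml4 (1.61), Ntrk2 (1.36), Ly6d (1.22), Ccr7 (1.16, a lymphocyte homing receptor), Susd3, Ces2e, Rbfa and Eif3f. The 7 lower ones were also the natriuretic peptide clearance receptor gene Npr3 (−1.42), Disp2 (−1.27), A3galt2 (−0.94), Mmp3 (−0.88), Slc5a3 (−0.82) and the arginine carrier gene Slc7a1 (−0.54). Susd3, Ces2e, Rbfa and Eif3f were named after their values were seen.

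**Figure D4:**
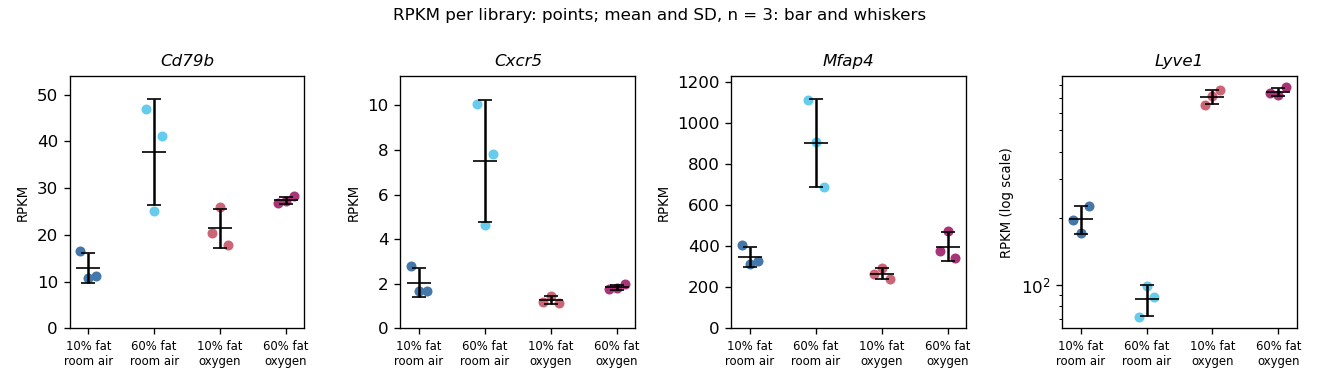
RPKM of 4 genes per library in the 4 groups, points for libraries, bars for means and whiskers for the SD (n = 3); the axis for Lyve1 is logarithmic. In room air Mfap4 averaged 901 on 60% fat and 348 on 10% fat, and Lyve1 86.4 and 198.

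Among the lists in room air, all 16 B cell markers were higher on 60% fat, 3 of them called over all genes and 16 adjusted over the list alone (median 1.22, adjusted p = 1.72e-18, adjusted p = 0.241 with an estimated correlation). T and NK cell markers rose as a list, 1 called over all genes and 10 adjusted over the list alone of 22 (median 0.39, adjusted p = 3.01e-09, adjusted p = 0.241 with an estimated correlation). Fibroblast markers did so too, 1 and 2 of 16 (median 0.23, adjusted p = 0.00276, adjusted p = 0.703 with an estimated correlation). Genes of fatty acid oxidation were higher, 1 called over all genes and 5 adjusted over the list alone of 25 (median 0.14, adjusted p = 9.42e-05, adjusted p = 0.210 with an estimated correlation). Genes of fatty acid synthesis were lower as a list, 0 called over all genes and 5 adjusted over the list alone of 22 (median −0.12, adjusted p = 0.000398, adjusted p = 0.241 with an estimated correlation). Chaperones of the endoplasmic reticulum were lower too, 0 and 17 of 20 (median −0.40, adjusted p = 2.91e-15, adjusted p = 0.241 with an estimated correlation). These 6 lists kept their calls without each library in turn. Scd1 stood at 365 ± 24.4 RPKM on 60% fat and 653 ± 179.6 on 10% fat (−0.81 ± 0.16, adjusted p = 0.0729). It was called with replicate numbers as a block within each exposure (adjusted p = 0.0213) and without 10% fat room-air replicate 1 (0.0135). Across alternatives its p ran from 0.00329 to 0.438. Fasn stood at 54.5 ± 2.87 and 77.5 ± 8.15 RPKM (−0.50 ± 0.13, adjusted p = 0.146; blocked adjusted p = 0.0364, and 0.0364 to 0.425 across alternatives). Srebf1 (−0.03 ± 0.08, adjusted p = 0.922), Sftpc (0.02 ± 0.22, adjusted p = 0.984) and Sftpb (−0.05 ± 0.19, adjusted p = 0.946) were not called.

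A further 6 lists were called in room air but lost the call when 1 library was left out. Type 2 markers were lower (median −0.15, adjusted p = 0.00899), but not without 60% fat room-air replicate 1 (adjusted p = 0.137) or 10% fat room-air replicate 2 (0.0597) or 3 (0.132). Clock genes were lower with all libraries (0.0305) and lost the call without the same 3, in that order (0.318, 0.0693 and 0.0656). Hypoxia and glycolysis genes (0.0348) and inflammatory genes (0.00138), both lower, lost the call without 60% fat room-air replicate 1 (0.241 and 0.122) or 10% fat room-air replicate 3 (0.258 and 0.693). Genes of oxidative phosphorylation (0.0055) and immediate early genes (0.00899), both higher, lost it without 60% fat room-air replicate 2 (0.696 and 0.269), the former also without 10% fat room-air replicate 1 (0.529) and the latter without 10% fat room-air replicate 2 (0.118). With an estimated correlation the adjusted p of these 6 lists lay between 0.241 and 0.849, and across alternatives between 3.63e-07 and 0.849. Over all genes 0 of their members were called; adjusted over the list alone there were 1 higher and 2 lower for the clock, 3 lower for hypoxia, 2 higher for the immediate early genes and 0 for the others. Both the clock and the hypoxia calls ended after median-ratio scaling (0.07) and quantile normalization (0.0714 and 0.068). Under the block, the alveolar macrophage (lower, blocked adjusted p = 0.0204), cell cycle (higher, 0.0386) and cardiac muscle lists (higher, 0.0169) were called as well, but not with the block and an estimated correlation together (adjusted p 0.424 to 0.810). Camera's direction was lower although the median was positive for the glucocorticoid (0.05), NRF2 (0.01), type 1 (0.02) and club lists (0.03), with adjusted p from 0.629 to 0.891. The glucocorticoid list was called without 60% fat room-air replicate 1 (0.0454) or 2 (0.0399) and the NRF2 list without 10% fat room-air replicate 1 (0.0387).

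In room air limma called 20 genes, 13 higher and 7 lower on 60% fat, with 1622 at an unadjusted p under 0.05 and 1874 (14.1%) without overlap, against 10% by chance. With the block it called 466, 316 higher and 150 lower, and after quantile normalization 66, of which 54.5% were higher against 65% in the main count. Lyve1 and Ccr7 kept their calls without each of the 12 libraries. The other 18 lost theirs without 60% fat room-air replicate 1 (adjusted p 0.0586 to 0.187). Of them 17 did so without 10% fat room-air replicate 2 (0.0759 to 0.142), 17 without 10% fat room-air replicate 3 (0.0969 to 0.210) and 16 without 60% fat room-air replicate 3 (0.0587 to 0.164). Leaving out single oxygen libraries, which share the estimate of spread, ended 6 to 14 of the 20 calls each (0.0511 to 0.0943). The count was 2 without 60% fat room-air replicate 1, 3 without 10% fat room-air replicate 2 or 3, 5 without 60% fat room-air replicate 3, 352 without 60% fat room-air replicate 2 and 112 without 10% fat room-air replicate 1. Among other settings it ran from 1 with the air libraries alone, where Lyve1 (adjusted p = 0.115) and Ccr7 (0.113) were not called, to 879 with sample weights. The main fit pools the spread with that of the oxygen libraries, which agreed more closely within a group. Its spread may therefore be too small for the air libraries.

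Under oxygen, the diet comparison called 1 gene. Dbn1, which encodes the actin-binding protein drebrin (chromosome 13, 55574789 to 55589437), averaged 15.4 ± 1.86 RPKM on 60% fat and 7.94 ± 0.760 on 10% fat (log2 change 0.91 ± 0.11, adjusted p = 0.0443). It lost the call in 8 of 12 omissions: without 60% fat oxygen replicate 1 (0.19) or 2 (0.259), 10% fat oxygen replicate 1 (0.255) or 3 (0.269), 10% fat room-air replicate 2 (0.0776) or 60% fat room-air replicate 1 (0.0721), 2 (0.0694) or 3 (0.0818). Fasn stood at 20.8 ± 4.01 and 26.7 ± 3.23 RPKM (−0.37 ± 0.13, adjusted p = 0.481) and Scd1 at 231 ± 13.5 and 225.3 ± 21.1 (0.04 ± 0.16, adjusted p = 0.981). Srebf1 stood at 28.7 ± 1.26 and 28.2 ± 2.13 (0.03 ± 0.08, adjusted p = 0.969). Sftpc stood at 9759.8 ± 1386 and 12414 ± 1593 (−0.35 ± 0.22, adjusted p = 0.746) and Sftpb at 1563 ± 457 and 1797 ± 178 (−0.24 ± 0.19, adjusted p = 0.82). At an unadjusted p under 0.05 limma gave 1076 genes, and 2425 (18.2%) did not overlap, against 10% by chance. With the block within exposures it called 102 genes, 31 higher and 71 lower. Dbn1 was not called without a filter (adjusted p = 0.0723), without a variance trend (0.0509), with a pseudocount of 0.1 (0.0538), with the oxygen libraries alone (0.0747) or after quantile normalization (0.0907).

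Genes of cholesterol synthesis were lower as a list on 60% fat under oxygen, 21 of 22 negative, with 0 called over all genes and 4 adjusted over the list alone (median −0.34, adjusted p = 4.24e-13, adjusted p = 0.351 with an estimated correlation). Club and secretory markers were lower, 0 and 3 of 14 (median −0.40, adjusted p = 4.26e-05, adjusted p = 0.390 with an estimated correlation), Scgb3a2 at −0.66 (adjusted p = 0.425, blocked adjusted p = 0.0283, and 0.0283 to 0.999 across alternatives). Also lower, with 0 to 2 members called over the list alone, were the type 2 (median −0.22, adjusted p = 1.03e-05), fatty acid synthesis (−0.10, adjusted p = 0.00537), fatty acid oxidation (−0.09, adjusted p = 0.000812), endothelial (−0.06, adjusted p = 0.00537) and adipocyte lists (−0.30, adjusted p = 0.000581). Their adjusted p with an estimated correlation lay between 0.351 and 0.631. B cell markers were higher, with 0 of 16 called either way (median 0.41, adjusted p = 9.31e-05, adjusted p = 0.627 with an estimated correlation). These 8 lists kept their calls in all omissions. A further 11 lists were called but each lost the call without at least 1 oxygen library: the cell cycle, p53, NRF2, MHC class II and T and NK cell lists, all higher, and the immediate early, type 1, ciliated, phospholipid, cardiac and skeletal muscle lists, all lower. Their adjusted p lay between 4.26e-05 and 0.034, and between 0.351 and 0.686 with an estimated correlation. Without 60% fat oxygen replicate 2 the NRF2 (0.726), p53 (0.0717), T and NK cell (0.268), type 1 (0.0577), phospholipid (0.065), cardiac (0.0855) and skeletal muscle calls (0.193) ended. Without 10% fat oxygen replicate 1 the NRF2 (0.133), type 1 (0.289), phospholipid (0.0819) and ciliated calls (0.0981) ended, and without replicate 2 of that group the p53 (0.123), cell cycle (0.192) and ciliated calls (0.255). Without 10% fat oxygen replicate 3 the MHC class II (0.216), T and NK cell (0.499), immediate early (0.0603) and skeletal muscle calls (0.176) ended. Leaving out 60% fat oxygen replicate 3 ended the MHC class II (0.241), type 1 (0.237) and ciliated calls (0.241), and leaving out replicate 1 of that group the cell cycle call (0.0788). Quantile normalization ended the type 1 and phospholipid calls (both 0.0716). Under the block the alveolar macrophage list was higher (blocked adjusted p = 0.0418; adjusted p = 0.698 with the block and an estimated correlation).

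Averaged over the exposures, the diet comparison called 3 genes, all higher on 60% fat: Mfap4 (log2 change 0.96 ± 0.12, adjusted p = 0.0266), Ccr7 (0.73 ± 0.09, adjusted p = 0.0266) and Cpxm1, a carboxypeptidase-like gene (chromosome 2, 130216511 to 130223365; 0.53 ± 0.07, adjusted p = 0.0458). At an unadjusted p under 0.05 there were 1342 genes. In 163 genes (1.22%) the diets did not overlap in either exposure and differed in the same direction in both, against 0.5% by chance. With the block limma called 198, 137 higher and 61 lower, among them Fasn (−0.43 ± 0.09, adjusted p = 0.153, blocked adjusted p = 0.0312, 0.0185 to 0.373 across alternatives). Scd1 (−0.38 ± 0.11, adjusted p = 0.283), Srebf1 (adjusted p = 0.997), Sftpc (adjusted p = 0.758) and Sftpb (adjusted p = 0.766) were not called. Each of the 3 calls ended without 60% fat oxygen replicate 1 (adjusted p 0.0741 to 0.168), 60% fat room-air replicate 1 (0.0574 to 0.137), 10% fat oxygen replicate 1 (0.105 to 0.135) or 3 (0.145 to 0.175), or 10% fat room-air replicate 2 (0.0596) or 3 (0.106 to 0.129). Those of Ccr7 (0.087) and Cpxm1 (0.112) also ended without 60% fat room-air replicate 3, and that of Cpxm1 without 60% fat oxygen replicate 3 (0.0772), 10% fat oxygen replicate 2 (0.0724) or 10% fat room-air replicate 1 (0.0564). Without 60% fat room-air replicate 2 the count was 218 and without 10% fat room-air replicate 1 it was 5. It was 0 without a variance trend (0.0543 to 0.0719 for these genes), 1 after quantile normalization (0.0686 for Mfap4 and Cpxm1) and 492 with sample weights. Without a filter Mfap4 (0.0655) and Cpxm1 (0.0675) were not called, and Cpxm1 was not called after median-ratio scaling (0.0502). B cell markers were higher as a list, 0 called over all genes and 16 adjusted over the list alone (median 0.83, adjusted p = 2.36e-19, adjusted p = 0.209 with an estimated correlation). T and NK cell markers were higher too, 1 and 7 of 22 (median 0.26, adjusted p = 4.57e-09, adjusted p = 0.304 with an estimated correlation). Chaperones of the endoplasmic reticulum were lower (−0.19, adjusted p = 1.09e-11, 3 of 20 adjusted over the list alone), as were cholesterol synthesis (−0.21, adjusted p = 2.91e-09) and fatty acid synthesis (−0.11, adjusted p = 1.55e-06, 6 of 22). Type 2 markers (−0.17, adjusted p = 2.01e-07) and clock genes (−0.09, adjusted p = 0.00633, 2 of 18) were lower too. The adjusted p of these 5 lists lay between 0.209 and 0.304 with an estimated correlation. These 7 lists kept their calls in all omissions; 8 further lists were called but lost the call without at least 1 library, the MHC class II, cell cycle, fibroblast and oxidative phosphorylation lists, all higher, and the adipocyte, club, hypoxia and phospholipid lists, all lower. Their adjusted p lay between 0.00101 and 0.0436, and between 0.209 and 0.695 with an estimated correlation. The omissions that ended some of them were 60% fat room-air replicates 1 (0.0954 to 0.180), 2 (0.134 to 0.676) and 3 (0.0599 to 0.109), 10% fat room-air replicates 1 (0.444), 2 (0.0519 to 0.0923) and 3 (0.107 to 0.193), 60% fat oxygen replicate 1 (0.05 to 0.0516) and 10% fat oxygen replicates 2 (0.0647) and 3 (0.107). Median-ratio scaling or quantile normalization ended the adipocyte, hypoxia, oxidative phosphorylation and phospholipid calls (0.0541 to 0.151). Under the block the cardiac muscle (lower, blocked adjusted p = 0.0359) and monocyte lists (higher, 0.0271) were called as well, but not with an estimated correlation (adjusted p = 0.392 and adjusted p = 0.593 with the block).

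The interaction asked whether the oxygen response differed between the diets. limma called 5 genes. Disp2, a gene of the dispatched family (chromosome 2, 118605455 to 118620911), averaged 6.08 ± 1.51 RPKM under oxygen and 3.45 ± 0.761 in air on 60% fat, and 2.02 ± 0.514 and 9.07 ± 1.98 on 10% fat (difference of log2 changes 2.65 ± 0.31, adjusted p = 0.0198). For Mmp3, a matrix protease (chromosome 9, 7445822 to 7455974), the values were 93.3 ± 4.51, 14.8 ± 3.45, 58.2 ± 5.86 and 27.3 ± 2.94 RPKM (1.56 ± 0.20, adjusted p = 0.024). Lyve1 rose to 746 ± 29.5 RPKM under oxygen on 60% fat and to 706 ± 52.7 on 10% fat from its unequal levels in air (1.28 ± 0.18, adjusted p = 0.0309). Slc7a1 (chromosome 5, 149138986 to 149211480) had a difference of 0.70 ± 0.10 (adjusted p = 0.0483). The sulfotransferase gene Sult1a1 (chromosome 7, 133816384 to 133819871) had one of −0.94 ± 0.13 (adjusted p = 0.0282), with 35.0 ± 1.89 and 47.6 ± 2.83 RPKM on 60% fat and 55.3 ± 4.29 and 38.8 ± 3.82 on 10% fat. Fasn (0.13 ± 0.19, adjusted p = 0.84), Srebf1 (0.06 ± 0.11, adjusted p = 0.898), Sftpc (−0.36 ± 0.31, adjusted p = 0.732) and Sftpb (−0.19 ± 0.27, adjusted p = 0.851) were not called. Nor was Scd1 (0.84 ± 0.22, adjusted p = 0.243; 0.04 without 10% fat room-air replicate 1, and 0.0252 to 0.452 across alternatives). At an unadjusted p under 0.05 there were 1371 genes, and with the block limma called 243, 89 with a positive and 154 with a negative difference. All 5 calls ended without 10% fat oxygen replicate 1 (adjusted p 0.109 to 0.190) or 3 (0.0926 to 0.157), 60% fat oxygen replicate 1 (0.102 to 0.135) or 2 (0.082 to 0.196), 10% fat room-air replicate 3 (0.0624 to 0.155) or 60% fat room-air replicate 3 (0.0607 to 0.105). All but that of Disp2 ended without 60% fat oxygen replicate 3 (0.0858 to 0.154). Those of Lyve1 and Slc7a1 without 10% fat oxygen replicate 2 (0.0806), those of Mmp3, Slc7a1 and Sult1a1 without 10% fat room-air replicate 2 (0.0584 to 0.105), and that of Slc7a1 without 60% fat room-air replicate 1 (0.110) ended too. The count was 43 without 60% fat room-air replicate 2, 41 without 10% fat room-air replicate 1 and 368 with sample weights. Lyve1 was not called without a filter (0.0626) or after median-ratio scaling (0.0734), Mmp3 after quantile normalization (0.0513), and Slc7a1 with a pseudocount of 1 (0.0601) or robust variances (0.0519).

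Of the 35 tested lists, 12 were called for the interaction. Genes of fatty acid oxidation had a lower log2 change under oxygen on 60% fat (list medians −0.20 on 60% fat and 0.06 on 10% fat), with 21 of 25 differences negative, 0 called over all genes and 8 adjusted over the list alone (median −0.26, adjusted p = 2.65e-07). This was the only list called with an estimated correlation (adjusted p = 0.0497), and with the block added that call ended (adjusted p = 0.342). B cell markers had a more negative response on 60% fat in 16 of 16 cases, 3 of them adjusted over the list alone (median −0.78, adjusted p = 4.84e-07, adjusted p = 0.756 with an estimated correlation). So had T and NK cell markers (−0.25, adjusted p = 0.000894, 1 of 22 adjusted over the list alone) and cardiac muscle markers (−0.89, adjusted p = 0.000928, 2 of 10). Immediate early genes, with positive medians in both diets (0.77 on 60% fat and 1.20 on 10% fat), rose less on 60% fat (difference −0.51, adjusted p = 3.18e-06, 3 of 13). Chaperones of the endoplasmic reticulum had a less negative response, 7 of 20 adjusted over the list alone (median 0.42, adjusted p = 2.65e-07); with an estimated correlation the adjusted p of each of these 4 lists was 0.756. These 6 lists kept their calls in all omissions. The other 6 were the cholesterol synthesis, endothelial, fibroblast, club and ciliated lists, all negative, and the inflammatory list, positive, each with an adjusted p of 0.756 with an estimated correlation. Adjusted over the list alone, 2 endothelial, 1 fibroblast and 1 inflammatory gene were called and 0 in the others. The cholesterol synthesis call ended without 60% fat oxygen replicate 1 (0.0582). The 5 others ended without 10% fat room-air replicate 3 (0.0736 to 0.212). Some of them also ended without 60% fat oxygen replicate 3 (0.0778 to 0.146), 60% fat room-air replicate 1 (0.0674 to 0.0977) or 2 (0.104 to 0.367), 10% fat oxygen replicate 1 (0.0931 to 0.189) or 2 (0.138), or 10% fat room-air replicate 1 (0.194 to 0.388) or 2 (0.112). Quantile normalization ended the ciliated, club, endothelial and fibroblast calls (0.0575 to 0.0681), and median-ratio scaling the ciliated call (0.0559). Under the block the alveolar macrophage list (positive, blocked adjusted p = 0.00261) and the oxidative phosphorylation list (negative, 0.0427) were called as well, but not with an estimated correlation (adjusted p = 0.566 and adjusted p = 0.583 with the block).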

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

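The tests on blood and on cardiac muscle and the count over all splits that part every pair were chosen only after the results were seen. The other splits of the samples were chosen before. The test on lymphoid tissue was chosen after the B cell pattern was seen, with its limits set before that test was run. Each result of this part stands here because the oxygen response differed between the diets in a test of the difference itself, and each value is the log2 change on 60% fat minus that on 10% fat. Among genes, the difference was 2.65 for Disp2, 1.56 for Mmp3, 1.28 for Lyve1, 0.70 for Slc7a1 and −0.94 for Sult1a1. For each of these genes the mean log2 difference between the diets had opposite signs in air and under oxygen. In air Disp2, Mmp3, Lyve1 and Slc7a1 were called for diet and Sult1a1 was not. Under oxygen Dbn1 alone was called for diet, so none of these genes differed detectably there. A reversed order of the diets under oxygen is therefore not established for any of them. Among lists, median differences were positive for chaperones of the endoplasmic reticulum (0.42) and inflammatory genes (0.55). They were negative for genes of fatty acid oxidation (−0.26) and cholesterol synthesis (−0.23), immediate early genes (−0.51), and markers of B cells (−0.78), T and NK cells (−0.25), cardiac muscle (−0.89), endothelium (−0.26), fibroblasts (−0.17), club cells (−0.41) and ciliated cells (−0.22). Of these 12 lists, 1 kept its call with an estimated correlation, that of fatty acid oxidation (adjusted p = 0.0497), and it lost it with the replicate block added (adjusted p = 0.342).

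For the interaction, 2 of 100 splits drawn from 200 (diet labels exchanged within each exposure, the real one included) gave as many genes as the real 5. The highest other count was 41, several times the real one, which points to a structure of the samples other than diet. Of all 32 splits that part every pair of equal replicate numbers, as the real one does, 1 gave as many, the real one itself, and the highest other count was 3. That 3 came from the real diet grouping with the diet labels exchanged under oxygen only. Its interaction is the average diet effect of the real labels, so that 3 is no measure of chance. The share was under 0.05 in both comparisons, and 1 of 32 is the smallest that the second can give. Exchanged diet labels test for no diet effect of any kind rather than for no interaction. These shares therefore do not exclude chance for the interaction as such, and several single omissions ended all 5 calls. For the average over exposures, 4 of the 100 gave as many as the real 3, with 50 as the highest other count, again a sign of such a structure. Of the 32 that part every pair, 2 gave as many, with 5 as the highest other count, a share above 0.05. That 5 came from the same split with labels exchanged under oxygen only, whose average is the interaction of the real labels. The remaining ones gave 0. Since that split keeps the real diet grouping, the share does not decide, and chance stays open for the average. The comparisons of 3 against 3 libraries have 10 splits and cannot give a share under 0.05. Their real and highest other counts were 8370 and 0 for oxygen on 60% fat, 7923 and 0 for oxygen on 10% fat, 1 and 2 for diet under oxygen, and 20 and 102 for diet in air. The 102 came from a split that parts 1 of the 3 pairs and points to a structure of the samples; the 3 other splits that part every pair gave 0.

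The 16 B cell markers were higher in 60% fat lungs in room air, and all of them had passed the filter on low values in this tissue; the list scores per library were 1.33, 0.17 and 0.99 on 60% fat and −0.00, −0.52 and −0.49 on 10% fat, so no library overlapped. Lymphoid tissue in the sampled piece may account for it. Of the genes chosen for lymphoid stroma and vessels only Cxcl13 was tested, and its difference of −0.0594 had a standard error of 0.797 (0.506 over pairs of equal replicate numbers), too wide to decide. Blood left in the lung could also raise leukocyte genes. The mean of the neutrophil list differed by 0.156 (median −0.12) with a standard error of 0.6225, or 0.0411 over such pairs. Over pairs the upper 95% limit was 0.333, below the 0.5 set for this test after the results were seen. By that rule it speaks against blood as the whole cause. Without pairs the spread is too wide to decide, and the list measures neutrophils, not B cells carried in blood, so blood stays open. The erythroid list, at 0.317 with a standard error of 0.992 over pairs, decided nothing, and a biological effect of the diet stays open.

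All 10 cardiac muscle markers fell under oxygen in both diets. Chance variation in how much cardiac muscle was taken with the lung was tested by moving pairs of equal replicate numbers, 3 against 3. The list score gave a two-sided exact permutation p = 0.1, the smallest that 3 pairs against 3 can give, so that test cannot decide. The pair scores were 1.45, 1.22 and 1.38 in air and −1.09, −1.99 and −0.968 under oxygen. The gap between the exposures was wider than the spread within either. The pattern was picked from these same values, so the gap is no separate test and chance variation stays open. Less such muscle taken from all oxygen lungs may explain the fall. The score differed by −2.32 ± 0.301 on 10% fat and −3.08 ± 0.362 on 60% fat. Such sampling cannot be told apart from a fall of these transcripts under oxygen, since both would part the same libraries.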

How the results depend on the processing

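The replicate block within each exposure, alone and with an estimated correlation for lists, and the omission of every gene with a failed estimate were chosen after the data were seen, and the other settings before; the alternatives on read counts were not run, since the table examined holds RPKM only. Both oxygen counts stayed within 1.5 times of 8370 and 7923 under every setting run except the 2-fold minimum. With that minimum the counts were 1988 and 1688 for oxygen (60% and 10% fat), 0 for diet under oxygen (main count 1), 13 for diet in air (main count 20), 0 for the average (main count 3) and 3 for the interaction (main count 5), by construction of a stricter rule. A pseudocount of 0.1 gave 0 for diet under oxygen. No filter gave 12 for diet in air, with more genes tested. An RPKM of at least 5 gave 2 for diet under oxygen and 5 for the average. Median-ratio scaling gave 37 for diet in air and quantile normalization 66, with 0 under oxygen and 1 for the average. Without a variance trend diet under oxygen and the average fell to 0, and robust variances gave 2 under oxygen. Sample weights gave 44 for diet under oxygen, 879 in air, 492 for the average and 368 for the interaction. The air libraries alone gave 1 for diet in air. That fit had fewer samples to estimate the spread. It also left out the oxygen libraries, which agreed more closely within a group (r from 0.990 to 0.995) than the air libraries (0.980 to 0.988). Which of these lowered the count was not tested. Replicate numbers as a block gave 6, 60, 16 and 17 for diet under oxygen, diet in air, the average and the interaction, and as a block within each exposure 102, 466, 198 and 243. All genes called for diet or the interaction without a block were called in both block fits. At an unadjusted p under 0.05 limma gave 1076 genes for diet under oxygen and 1342 for the average. Leaving out 1 library at a time gave 7474 to 8454 and 7020 to 8457 for oxygen, 0 to 3 for diet under oxygen, 2 to 352 in air, 0 to 218 for the average and 0 to 43 for the interaction. The correlation of the oxygen responses ran from 0.905 to 0.934 with 1 library left out and from 0.917 to 0.936 under the other settings. Sftpc on 60% fat had a change of 6.59e-05 (adjusted p = 0.999) after quantile normalization in place of −1.38, since the most abundant genes are set to the same values there; for Sftpc on 10% fat it gave an adjusted p of 0.999, and for Scgb1a1 a change of 0 in both diets. Median-ratio scaling moved the median of all genes from −0.0934 to −0.00476 on 60% fat and from −0.0791 to −0.00346 on 10% fat, and with it the share of oxygen calls that were higher from 41.9% to 49.9% and from 42.5% to 49.7%. Of 22701 gene values under other settings 21902 kept direction and side of the threshold, 325 lost a call, 360 gained one, 113 moved and 1 reversed. Of 3640 list values 3112 kept theirs, 272 lost a call, 120 gained one, 136 moved and 0 reversed; with the block and an estimated correlation together 0 lists were called for diet or the interaction. Where no construction is named, the cause was not tested. Depth limits the precision of genes with few reads, and how many calls it cost was not tested.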

Other observations

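The gene families and single genes of this part were chosen after their values were seen, and both tests on the breadth of the oxygen response were too. Keratins, the filament proteins of epithelia, rose under oxygen in 8 of 11 tested cases in each diet with none falling. Krt8 went from 158 ± 31.5 to 671 ± 32.1 RPKM on 60% fat (log2 change 2.10 ± 0.14, adjusted p = 1.52e-07) and Krt18 by 2.08 ± 0.13. Replication-dependent histones fell in 11 of 15 cases on 60% fat and 9 of 15 on 10% fat, with 0 and 1 rising (medians −1.32 and −1.27). Cytoplasmic aminoacyl-tRNA synthetases rose in 14 of 17 and 13 of 17 cases with 1 falling in each (medians 0.74 and 0.30), and proteasome subunits in 19 and 21 of 38 with 4 falling in each (medians 0.23 and 0.24). Potassium channel genes fell in 19 of 38 cases in each diet and rose in 6 (medians −0.45 and −0.43). After quantile normalization 17 fell and 11 rose on 60% fat and 15 fell and 10 rose on 10% fat (medians −0.17 and −0.20). The medians of these 5 families kept their sign under median-ratio scaling and quantile normalization.

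Cirbp and Rbm3, known as cold-inducible RNA-binding protein genes, were higher under oxygen, and several heat shock genes lower. Cirbp (chromosome 10, 79630586 to 79634398) went from 19.2 ± 5.08 to 118 ± 14.6 RPKM on 10% fat (2.62 ± 0.17, adjusted p = 1.89e-07) and from 29.3 ± 5.67 to 105 ± 1.72 on 60% fat (1.84 ± 0.17, adjusted p = 2.07e-06). Rbm3 (chromosome X, 7716101 to 7722928) changed by 2.56 ± 0.08 and 2.15 ± 0.08. The heat shock genes Hspa8 (−2.24 ± 0.23 on 10% fat, −1.37 ± 0.23 on 60% fat), Dnaja1 (−2.59 ± 0.19, −1.70 ± 0.19) and Chordc1 (−2.57 ± 0.14, −1.63 ± 0.14) were lower. In the family of 67 heat shock and DnaJ genes, 31 fell and 19 rose on 10% fat. On 60% fat 25 fell and 17 rose, and 20 fell and 22 rose after median-ratio scaling. The differences between the diets were not called for Cirbp (adjusted p = 0.293), Rbm3 (0.276), Hspa8 (0.399), Dnaja1 (0.277) or Chordc1 (0.164). Body temperature was not recorded in the labels, and no explanation was tested.

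Oxygen called most tested genes in both diets, and the composition and depth of the libraries were weighed as technical causes of such breadth. A few genes taking most of the counts could shift all others together, and Scgb1a1 made up 20.4% of the summed RPKM in 60% fat room-air lungs. RPKM is scaled by gene length, so this is not its share of the reads. Median-ratio scaling, which removes such a shift, moved the median change of all genes to near 0 and left 8480 and 8047 genes called (60% and 10% fat) in place of 8370 and 7923, which argues against a shift as the whole cause. Rough mean depth was lower under oxygen (22.2 M reads on 60% fat and 22.8 M on 10% fat) than in air (25.5 and 25.7 M). A difference in depth could act on genes with few reads. Of the 10367 genes with an RPKM of at least 5 in 3 libraries 64.6% and 61.3% were called, against 62.8% and 59.5% of all. The calls were thus not confined to genes with few reads. Genes with more reads are measured more precisely, so these shares do not exclude some effect of depth. A difference in batch or handling between the exposures was not weighed and would part the same libraries as oxygen. Libraries of equal replicate number correlated within an exposure (r from 0.293 to 0.486) but little across exposures (−0.131 to 0.22). A biological response to oxygen, the factor by which the labels part these groups, remains as a hypothesis beside it, found and tested on the same data.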
